A study of Mus musculus with 12 samples.

How the data were processed

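Total RNA of mouse embryonic fibroblasts was sequenced in 12 libraries. Per the labels, the cells were secondary 1B fibroblasts, which carry reprogramming factors that doxycycline (dox) switches on, and they received a control siRNA (siControl), an siRNA against c-Myc (siMyc, gene Myc) or an siRNA against Gcn5 (siGcn5, gene Kat2a), either without dox or with dox for 2 days. These labels give 6 groups of 2 libraries. The labels mention both siRNA pools and individual siRNAs and do not tie either kind to these libraries. No label ties replicates to separate cultures, so p-values measure the spread between these libraries, which may be technical. Per the labels' protocols, ribosomal RNA was depleted, stranded libraries were made from total RNA and reads were taken on an Illumina HiSeq instrument.

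The authors deposited 1 table per library with 1 RPKM value (reads per kilobase of transcript, scaled to the library's depth) for each of 23284 gene symbols. Per the submitters' processing notes, the mouse build was mm9 and the tools included TopHat2 2.0.9, Bowtie 0.12.8, HTSeq, edgeR and affy, with no version for the last 3. Which tool made which value, the gene annotation, the handling of strand and the filters are not given in the sources used here. The RPKM values as deposited were used with no further scaling. RPKM divides by each library's total, so a change in total RNA per cell is not measured, and a rise of abundant genes lowers the values of all others. Of the gene symbols, 2496 were listed at 0 in every library. The values are per gene, so the use of single exons was not analysed here.

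Within a library the RPKM of a gene is a whole multiple of what 1 read is worth for that gene, which gave back whole reads for all 20788 genes with a value, with a tolerance of 0.05 read. In a simulated check on 3000 genes, 99.8% of genes came back with the exact reads. Gene reads per library ran from 65.5 M to 188 M. Replicates correlated at Spearman 0.990 to 0.997 across genes. Their recovered reads differed by far more than sampling noise, with a chi-square per degree of freedom of 39.2 to 116, so no pair was treated as 1 library. Reads that match several near-identical genes could have been split or dropped in counting, so values of ribosomal protein genes, Prl2c3 and Prl2c4, and Bglap and Bglap2 are uncertain.

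Genes with an RPKM of 1 or more in at least 2 of the 12 libraries were tested, which left 13175 genes. The test was limma 3.58.1 in R 4.3.3 with an intensity trend on log2(RPKM + 1), over all 12 libraries with 1 term per group, which left 6 residual degrees of freedom and added 4.17 prior degrees of freedom. A gene was called at a two-sided Benjamini-Hochberg adjusted p under 0.05. All log2 changes are on the log2(RPKM + 1) scale, which understates the change of low genes, and all adjusted p-values are from limma. A gene given as at log2 followed by a value had that log2 change, or difference between siMyc and siGcn5, in the comparison at hand. The 8 comparisons were dox in siControl, siMyc and siGcn5 each against siControl without and with dox, the interaction of each siRNA with dox, and siMyc against siGcn5 with dox. Values after ± are SDs over 2 libraries.

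Members of 22 gene lists were fixed by name: SAGA complex, Myc network, splicing regulators, core spliceosome, ribosome biogenesis, ribosomal proteins, nucleotide and one-carbon synthesis, glycolysis, proliferation, mesenchymal and fibroblast, epithelial, pluripotency, interferon response, p53 and arrest, endoplasmic reticulum (ER) and amino acid stress, cholesterol synthesis, inflammatory cytokines, and markers of endothelial, blood, skeletal muscle, neural and adipocyte cells. Of 602 members, 599 were found and 520 tested. Counts for a list are over its tested members, which leave out many of the pluripotency genes and cell type markers. Each list was compared with all other genes tested by limma's camera with a preset correlation of 0.01, with p-values adjusted over the 22 lists of a comparison. No list call held with an estimated correlation. Counts of called members are given over all genes tested and, where they differ, adjusted over the list alone. The size of the dox response was compared between siControl and each siRNA over genes called for dox in the third arm, with limma's fry on the interaction, adjusted over the 2 comparisons. Fry asks whether genes move, on balance, 1 way and does not compare them with other genes. Overlaps of the siMyc and siGcn5 effects were set beside 100 simulations of unchanged groups against the same controls and beside the overlap of independent lists.

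Named genes followed a rule. It took Myc, Kat2a, Pou5f1, Sox2 and Klf4, up to 10 of the largest rises and falls among called genes whose groups did not overlap and whose higher group had a mean RPKM of at least 2 (up to 5 each way for interactions), and up to 4 called members of each list with the largest change, or the member with the smallest p where none was called. Predicted genes and small RNA genes were passed over for the largest changes. The text leaves out some genes that the rule takes. The groups, comparisons, main test, lists, this rule and the following other settings were chosen before the data were examined. The settings were a pseudocount of 0.1, no filter, a mean RPKM of at least 5, median-ratio scaling, quantile normalization, the replicate number as a block, no intensity trend, array weights, only the groups compared, a 2-fold minimum, an estimated correlation and each library left out in turn. Chosen after seeing the data were limma voom on the recovered reads, reads thinned to the shallowest library, and the genes left out whose 3′ UTR holds a sequence tied to an siRNA.

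That last setting rests on 7-base sequences (heptamers) in 3′ UTRs, since an siRNA can lower transcripts that pair with its seed. For 11057 genes with a 3′ UTR in GENCODE M21 (GRCm38, used for sequence and not for coordinates), the siGcn5 minus siMyc difference was regressed on each of 16103 heptamers that occurred in at least 50 genes, with 3′ UTR length and base composition as covariates. The fit run first, which also held squares and mean expression and took a one-sided threshold, gave 9 heptamers that marked lower values in siGcn5 and 2 in siMyc without dox. Of the 9, 6 occur in the Kat2a transcript and 2 passed again with dox in that fit. Both siMyc heptamers occur in the Myc transcript and passed again. Of all heptamers tested, 15.9% occur in the Kat2a transcript and 11.8% in the Myc transcript. The 2 siMyc heptamers are the same stretch shifted by 1 base, and several of the 9 overlap likewise, so they are not separate hits. A gene is said to hold an siRNA heptamer where its longest 3′ UTR contains at least 1 of the 9 or of the 2. Across all genes with a 3′ UTR, 40.1% hold an siGcn5 heptamer and 12.8% an siMyc heptamer. Holding one therefore does not by itself mark a gene as a seed target. In every comparison, the setting without heptamer genes left out all 4929 genes that hold a heptamer of either siRNA. Of these, 1416 hold an siMyc heptamer. Fewer list members were then tested, so a list call that ended does not by itself point to seed pairing.

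The procedure was tested on simulated data, 10 sets of 13175 genes with 200 changed. For siMyc with dox, 56.6% of genes changed by 0.5 log2 were recovered, 92.8% at 1 and 99.4% at 2, and 5.42% of 1752 calls were false. For the interaction with siMyc the shares were 24.9%, 79.0% and 98.3%, with 4.68% of 1411 calls false. Simulated genes and libraries were drawn independently, with far fewer genes changed than were called in the real comparisons. The shares recovered and false therefore need not hold there. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.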

Results

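RNA was sequenced from mouse embryonic fibroblasts in which dox switches on introduced reprogramming factors, treated with siControl, siMyc or siGcn5 and kept without dox or with dox for 2 days. Myc is a transcription factor and a reprogramming factor, and Gcn5 is the histone acetyltransferase of the SAGA coactivator complex. The study asked how both act on the early response to reprogramming factors, with a focus on regulators of splicing. Each of the 6 groups held 2 libraries. Recovered gene reads, in M per library (replicates 1 and 2), were 135 and 150 in siControl without dox, 133 and 97.3 in siControl with dox, 156 and 130 in siMyc without dox, 65.5 and 188 in siMyc with dox, 124 and 86.4 in siGcn5 without dox, and 102 and 92.5 in siGcn5 with dox. Between 11596 and 12338 genes had an RPKM of 1 or more in a library. Along the first principal component of the tested genes, which held 51.9% of the variance, siControl libraries without dox lay at −33.9 ± 0.94 and those with dox at 65.0 ± 2.3 (SD, n = 2).

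The targeted genes were lower in the libraries labelled for them. Myc RPKM was 19.6 ± 3.0 in siControl and 4.69 ± 0.16 in siMyc without dox, and 165 ± 14 and 21.6 ± 6.6 with dox (SD, n = 2), log2 changes of −1.85 (SE 0.20, adjusted p = 0.00060) and −2.91 (SE 0.20, adjusted p = 6.2e-07). Kat2a RPKM was 21.9 ± 1.6 in siControl and 1.65 ± 0.45 in siGcn5 without dox, and 54.4 ± 1.8 and 7.69 ± 2.0 with dox, log2 changes of −3.12 (SE 0.15, adjusted p = 1.6e-06) and −2.69 (SE 0.15, adjusted p = 2.9e-06). The other target also moved in each arm. Kat2a fell in siMyc with dox, to 18.8 ± 0.88 RPKM (log2 −1.49, adjusted p = 8.3e-06), and did not pass the test without dox (log2 −0.34, adjusted p = 0.129). Myc fell in siGcn5 without dox, to 8.20 ± 1.6 RPKM (log2 −1.17, adjusted p = 0.00061). With dox its value in siGcn5 was 116 ± 18 RPKM (log2 −0.51, adjusted p = 0.0464), a call that ended without any of the 4 siControl libraries (0.0515 to 0.185), either siMyc library without dox (0.0601) or siGcn5 replicate 1 with dox (0.256). Of the other reprogramming factors, Pou5f1 (Oct4) rose with dox in siControl from 1.12 to 268 RPKM, Sox2 from 0.318 to 32.1 and Klf4 from 12.0 to 105. RPKM does not separate the introduced copies of these genes from the cell's own. Without dox, Pou5f1 was at 2.55 ± 0.034 RPKM in siGcn5 against 1.12 ± 0.25 in siControl (log2 0.75, adjusted p = 0.0034), a call that held with any 1 library left out (0.00063 to 0.0333). With dox and siMyc, Pou5f1 fell to 110 ± 17 RPKM (log2 −1.28, adjusted p = 5.0e-05) and Sox2 to 16.9 ± 2.2 (log2 −0.89, adjusted p = 0.0042). Klf4 stood at 144 ± 4.6 RPKM (log2 0.46, adjusted p = 0.0184), a call that ended without siControl replicate 2 (0.148) or siMyc replicate 2 (0.0755). With dox and siGcn5, Pou5f1 was at 169 ± 44 RPKM (log2 −0.69, adjusted p = 0.0059), Sox2 at 19.5 ± 8.3 (log2 −0.75, adjusted p = 0.0163) and Klf4 at 75.4 ± 16 (log2 −0.48, adjusted p = 0.0207), and these calls ended without siGcn5 replicate 1, at 0.0513, 0.119 and 0.185. Without siGcn5 replicate 2 Sox2 was at log2 −1.17. The calls of Sox2 and Klf4 also ended without siControl replicate 1 (0.0979 and 0.147), and the 3′ UTR of Klf4 holds an siGcn5 heptamer.

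**Figure D1:**
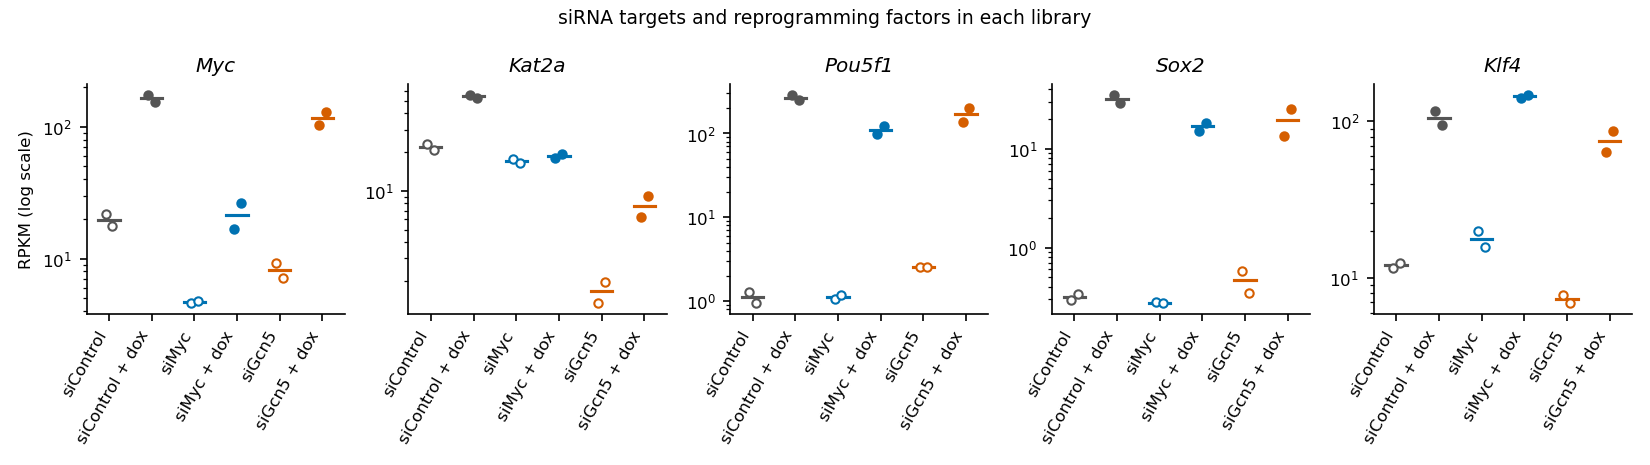
RPKM (log scale) of Myc, Kat2a, Pou5f1, Sox2 and Klf4 in each library, by siRNA, with open points without dox, filled points with dox and a line at each group mean (n = 2). Myc is at 21.6 RPKM in siMyc with dox against 165 in siControl with dox, and Kat2a at 7.69 in siGcn5 against 54.4.

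Dox in siControl cells asked what 2 days of factor induction did. The keratin genes Krt14 and Krt16 rose from near 0, from 0.0600 to 334 RPKM and from 0.0519 to 257 RPKM (adjusted p = 3.4e-11 and 2.3e-12), and Krtdap, Cnfn, Slurp1 and the water channel Aqp3 rose to mean RPKM between 85.4 and 178. Genes that fell included Postn, a matrix protein (151 ± 34 to 13.0 ± 0.031 RPKM, log2 −3.42, SE 0.18), Wisp2 (log2 −3.23), Fmod (log2 −2.92), Itga11 (log2 −2.66), the growth factor receptor Pdgfrb (log2 −2.62) and Isg15 (35.8 ± 4.6 to 2.64 ± 0.67 RPKM). In all, 9751 of 13175 genes were called, 6075 up and 3676 down. The median of all genes rose by 0.17 log2, and 62.3% of calls were rises, against 52.2% with median-ratio scaling and 49.9% with quantile normalization; the list tests compare each list with all other genes.

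By list, all 43 genes of ribosome biogenesis rose (median log2 1.57, adjusted p = 4.5e-11; adjusted p = 0.596 with an estimated correlation), led by Polr1b, a subunit of RNA polymerase I (5.98 to 31.8 RPKM), Lyar (log2 2.19), Polr1e (log2 2.16) and the nucleolar protein Nolc1 (log2 2.06). All 56 core spliceosome genes rose (median 0.86, adjusted p = 2.7e-10; adjusted p = 0.596 with an estimated correlation). Snrnp40 was at log2 1.50 and the small ribonucleoproteins Snrpa1 and Snrpg both at 1.39. Among 58 splicing regulators 43 rose, 6 fell and 9 did not pass the test (median 0.54, adjusted p = 0.00097; adjusted p = 0.561 with an estimated correlation). Rbm38 rose from 6.21 ± 0.49 to 38.7 ± 1.9 RPKM, the arginine methyltransferase Prmt5 from 28.8 ± 0.86 to 82.3 ± 1.5, and Hnrnpa1, which binds exonic and intronic silencers, from 277 ± 4.1 to 579 ± 35. Ribosomal protein genes rose in 46 of 53 cases (48 adjusted over the list alone), at a median of 0.48 (adjusted p = 0.00025; adjusted p = 0.812 with an estimated correlation). Rpl7a was at log2 0.86 and Rpl8 at 0.71. Of 30 genes of nucleotide and one-carbon synthesis 28 rose (median 1.26, adjusted p = 4.6e-06; adjusted p = 0.596 with an estimated correlation). Shmt1 was at log2 3.16 and the purine enzymes Ppat at 2.19 and Gart at 1.95. Of 35 proliferation genes 31 rose and 1 fell (median 1.01, adjusted p = 0.0021; adjusted p = 0.812 with an estimated correlation). Cdca7 was at log2 2.20 and the replication helicase subunits Mcm5 at 1.69 and Mcm7 at 1.67. Of 34 mesenchymal genes 31 fell and 1 rose (median −1.63, adjusted p = 1.6e-13; adjusted p = 0.561 with an estimated correlation). The collagen gene Col1a2 fell by 2.37 log2, and the exception was the proteoglycan Dcn, from 5.70 ± 1.6 to 101 ± 1.7 RPKM. Of 20 epithelial genes 18 rose and 1 fell (median 1.78, adjusted p = 4.0e-06; adjusted p = 0.561 with an estimated correlation). E-cadherin (Cdh1) went from 0.00865 to 17.0 RPKM and Krt8 from 0.674 to 125. Interferon response genes fell in 16 of 29 cases (15 adjusted over the list alone) and rose in none, at a median of −0.92 (adjusted p = 4.6e-05; adjusted p = 0.760 with an estimated correlation). Of 19 ER stress genes 9 fell and 2 rose (median −0.26, adjusted p = 0.0077; adjusted p = 0.654 with an estimated correlation). Ddit3 was at log2 −1.94 and Atf3 at 1.55, and of 15 inflammatory genes 10 fell and 1 rose (median −0.80, adjusted p = 0.0015; adjusted p = 0.596 with an estimated correlation and 0.0974 without genes that hold an siRNA heptamer). Cxcl12 was at log2 −2.44. Quantile normalization moved the medians of ribosomal protein and ER stress genes to 0.24 and −0.46 (0.30 and −0.43 with median-ratio scaling). Voom moved those of epithelial and interferon genes to 5.25 and −2.14 (3.66 and −1.91 with a pseudocount of 0.1).

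**Figure D2:**
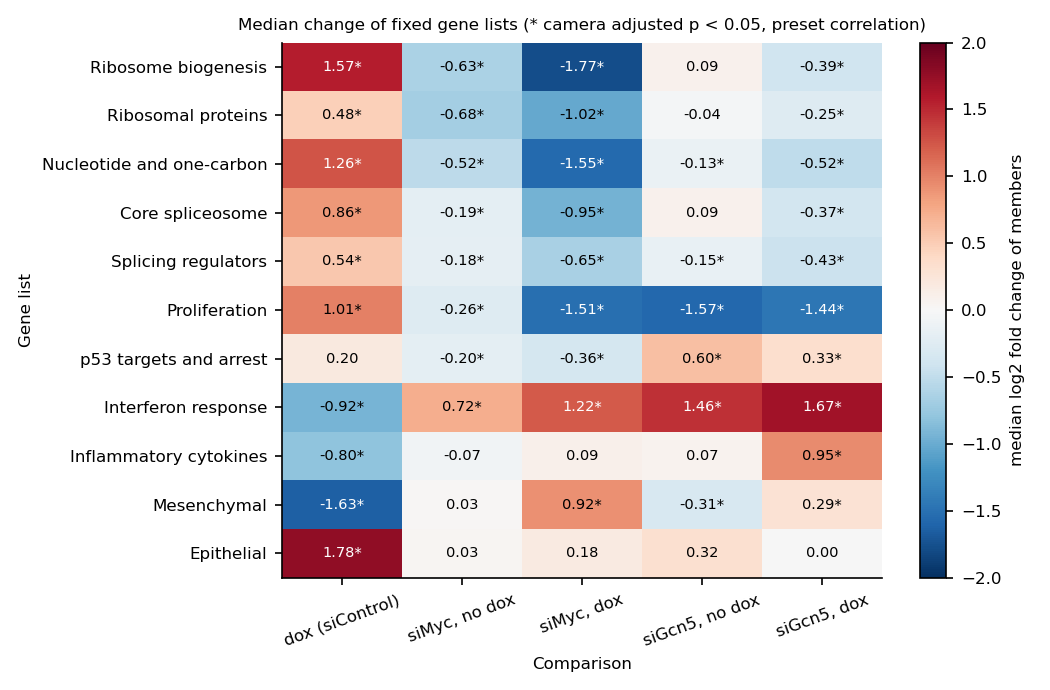
Median log2 change of 11 gene lists (vertical) in the response to dox in siControl and in the siMyc and siGcn5 effects without and with dox (horizontal), with the colour and the printed value giving the median on the log2(RPKM + 1) scale and a star marking an adjusted p under 0.05 with the preset correlation. Ribosome biogenesis is at 1.57 with dox in siControl and at −1.77 with siMyc and dox, and the medians of ribosome biogenesis, core spliceosome, ribosomal proteins and inflammatory genes with siGcn5 without dox change sign under another scaling.

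The siMyc effect without dox asked which genes depended on Myc before induction. Ribosomal protein genes fell in 52 of 53 cases (median −0.68, adjusted p = 1.1e-33; adjusted p = 0.246 with an estimated correlation, and a median of −0.32 under quantile normalization). Rplp0 was at log2 −0.89 and Rps9 at −0.86. Ribosome biogenesis genes fell in 40 of 43 (median −0.63, adjusted p = 3.0e-20; adjusted p = 0.246 with an estimated correlation), with Dkc1, which makes pseudouridine in RNA, at log2 −1.30 (SE 0.20) and Nop56 at −0.90. The other large falls were Gamt, the last enzyme of creatine synthesis (11.1 ± 1.2 to 1.48 ± 0.49 RPKM), Snrnp40, a U5 small ribonucleoprotein (26.0 ± 0.34 to 7.23 ± 1.5), the ferritin light chain Ftl1 (3025 ± 98 to 1046 ± 29), Ddit4 (log2 −1.49), Spp1 (log2 −1.44), Adi1 (log2 −1.51) and Ogn (log2 −1.53). Nkain4 (2.98 ± 0.47 to 16.5 ± 5.2 RPKM), the arginase Arg1 (log2 1.66), Flt4 (log2 1.62), Mfap5 (log2 1.49) and Nov (log2 1.41) rose. Adi1 and Ogn hold an siMyc heptamer in the 3′ UTR. Among called genes with a 3′ UTR, 18.2% of those that fell hold one, against 9.11% of those that rose. The heptamers were chosen on values of these libraries, which favours such a gap.

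In the other lists, 21 of 30 nucleotide and one-carbon genes fell and none rose (22 fell and 1 rose adjusted over the list alone; median −0.52, adjusted p = 1.3e-11; adjusted p = 0.246 with an estimated correlation). Mthfd1 was at log2 −1.03, Shmt2 at −0.88 and the spermidine synthase Srm at −0.87. Of 56 core spliceosome genes 13 fell (14 adjusted over the list alone) and none rose (median −0.19, adjusted p = 4.0e-07; adjusted p = 0.436 with an estimated correlation). Snrpf was at log2 −0.54 beside Snrnp40. Among 58 splicing regulators 13 fell, 1 rose and 44 did not pass the test (median −0.18, adjusted p = 1.1e-06; adjusted p = 0.246 with an estimated correlation). Hnrnpul1 was at log2 −0.77 and Hnrnpa1 at −0.74. Glycolysis genes fell in 8 of 20 cases (10 adjusted over the list alone; median −0.23, adjusted p = 0.00096; adjusted p = 0.246 with an estimated correlation, and a median of −0.09 under quantile normalization). Aldoa was at log2 −0.75 and Pgam1 at −0.51, and both hold an siMyc heptamer. Among 25 p53 and arrest genes 12 fell and 2 rose (median −0.20, adjusted p = 0.00015; adjusted p = 0.246 with an estimated correlation). Eda2r was at log2 −1.15. Only 2 of 35 proliferation genes fell (median −0.26, adjusted p = 0.0053; adjusted p = 0.802 with an estimated correlation), and this list call ended without siControl replicate 1 or siMyc replicate 2, at 0.0940 for either. Of 29 interferon genes 1 was called, Zbp1, and none when adjusted over the list alone (median 0.72, adjusted p = 0.0022; adjusted p = 0.802 with an estimated correlation). The call of Zbp1 ended without any of the 4 libraries compared (0.0985 to 0.135). Mesenchymal genes went both ways, 5 up and 6 down of 34 (median 0.03, adjusted p = 0.958). Dcn was at log2 0.92 and N-cadherin (Cdh2) at 0.91. Of 22 SAGA genes 3 fell, and none when adjusted over the list alone (median −0.06, adjusted p = 0.0567). With the replicate block this list passed as lower (adjusted p = 0.0446). The list passed as lower with no filter (0.0197), median-ratio scaling (0.0426), quantile normalization (0.0372), array weights (0.0444) and thinned reads (0.0397), and without siMyc replicate 1 (0.0190) or either siGcn5 library with dox (0.0361 for each). Of 13175 genes 3098 were called, 1686 up and 1412 down. The count was 1072 without siMyc replicate 1, 1272 without siControl replicate 1 and 1387 without siControl replicate 2.

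The siMyc effect with dox asked which parts of the induced response needed Myc. Most of the lists that rose with dox in siControl were lower with siMyc, and the epithelial list was not (median 0.18). All 43 ribosome biogenesis genes fell (median −1.77, adjusted p = 4.9e-15; adjusted p = 0.376 with an estimated correlation). Lyar was at log2 −2.51, Dkc1 at −2.49 and Polr1b at −2.46. Of 56 core spliceosome genes 55 fell (median −0.95, adjusted p = 4.3e-14; adjusted p = 0.376 with an estimated correlation). Snrnp40 was at log2 −2.63, Snrpg at −1.88 and Snrpa1 at −1.66. Among 58 splicing regulators 44 fell, 5 rose and 9 did not pass the test (median −0.65, adjusted p = 4.2e-07; adjusted p = 0.252 with an estimated correlation). Prmt5 went from 82.3 ± 1.5 to 21.2 ± 3.8 RPKM (log2 −1.92, SE 0.11, adjusted p = 2.9e-07), Hnrnpa1 from 579 ± 35 to 159 ± 28 (log2 −1.87, SE 0.14, adjusted p = 1.1e-06), Hnrnpa2b1 from 344 ± 8.3 to 126 ± 5.2 and Rbm38 from 38.7 ± 1.9 to 13.5 ± 0.054. Among single genes, Ccnb1ip1 (20.4 ± 0.018 to 1.01 ± 0.60 RPKM), Smpdl3b (23.6 ± 0.41 to 1.57 ± 1.1), the carbonic anhydrase Car12 (25.1 ± 1.8 to 1.97 ± 1.4) and the glycine decarboxylase Gldc (8.12 ± 0.90 to 0.415 ± 0.20) were among the large falls. Nkain4 (1.30 ± 0.44 to 32.7 ± 2.2 RPKM), the placental growth factor Pgf (1.98 ± 0.50 to 41.5 ± 3.8), the Wnt inhibitor Notum (0.776 ± 0.12 to 24.3 ± 1.8), Fxyd6 (log2 3.67), Cdsn, an adhesion protein of cornified epithelium (log2 3.39), and Edn2 (log2 3.18) were among the large rises.

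All 53 ribosomal protein genes fell with siMyc and dox (median −1.02, adjusted p = 4.3e-14; adjusted p = 0.430 with an estimated correlation, and a median of −0.51 under quantile normalization). Rplp0 went from 2360 ± 70 to 922 ± 129 RPKM and Rps9 was at log2 −1.37. Of 30 nucleotide and one-carbon genes 29 fell (median −1.55, adjusted p = 1.8e-09; adjusted p = 0.376 with an estimated correlation). Shmt1 was at log2 −3.34, Mthfd1 at −2.51, Gart at −2.47 and Cad at −2.45. Proliferation genes fell in 34 of 35 cases (median −1.51, adjusted p = 1.6e-07; adjusted p = 0.430 with an estimated correlation). Cdca7 was at log2 −2.73, the spindle checkpoint kinase Bub1b at −2.20 and Mcm5 at −2.13. Mesenchymal genes rose in 28 of 34 and fell in 1 (median 0.92, adjusted p = 1.3e-06; adjusted p = 0.376 with an estimated correlation). The matrix protein Sparc was at log2 2.06, the collagen cross-linking enzyme Lox at 1.56 and Col1a1 at 1.48. Interferon genes rose in 18 of 29 (17 adjusted over the list alone; median 1.22, adjusted p = 0.0046; adjusted p = 0.656 with an estimated correlation, and a median of 2.06 with a pseudocount of 0.1 and 2.34 with voom). Isg15 went from 2.64 ± 0.67 to 21.8 ± 2.4 RPKM, Usp18 at log2 2.64 and Irf7 at 2.41. Of 20 glycolysis genes 14 fell and 3 rose (median −0.51, adjusted p = 0.0141; adjusted p = 0.376 with an estimated correlation). Ldha was at log2 −1.59. Of 25 p53 and arrest genes 16 fell and 5 rose (17 and 6 adjusted over the list alone; median −0.36, adjusted p = 0.0387; adjusted p = 0.430 with an estimated correlation). Eda2r was at log2 −1.77 and the cell cycle inhibitors Cdkn1c at 2.07 and Cdkn2b at 1.55. SAGA genes fell in 12 of 22 cases (11 adjusted over the list alone) and rose in 2 (median −0.23, adjusted p = 0.0387; adjusted p = 0.376 with an estimated correlation). Kat2a itself was among them, with Taf5l at log2 −1.26, Sf3b3 at −1.11 and Ccdc101 at −1.08. ER stress genes rose in 12 of 19 and fell in 3 (median 0.51, adjusted p = 0.0414; adjusted p = 0.500 with an estimated correlation). Ddit3 was at log2 1.50. Epithelial genes went both ways, 10 up and 4 down of 20 (median 0.18, adjusted p = 0.299). Krt18 was at log2 1.61 and Cdh1 at −1.57. Quantile normalization ended the calls of glycolysis (adjusted p = 0.0734), p53 and arrest (0.0688) and SAGA (0.0533). A mean RPKM of at least 5 ended those of p53 and arrest (0.0956) and ER stress (0.101). Leaving out genes that hold a heptamer of either siRNA ended all 4 (0.0713, 0.0536, 0.140 and 0.160 for glycolysis, p53, SAGA and ER stress). The ER stress median was then 0.30, while those of glycolysis, p53 and SAGA stayed within 1.5 times of those reported. The ER stress call also ended without siControl replicate 2 (0.0506) or siMyc replicate 1 (0.0677), and the SAGA call without siMyc replicate 2 (0.0542). In all, 9866 of 13175 genes were called, 4973 up and 4893 down. Of the genes named for this effect, Car12 holds an siMyc heptamer. Among called genes with a 3′ UTR, 13.9% of those that fell hold one, against 11.8% of those that rose.

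The siGcn5 effect without dox asked which genes depended on Gcn5 before induction. Cell cycle genes were lower and interferon and p53 genes higher. Proliferation genes fell in 33 of 35 cases (median −1.57, adjusted p = 3.7e-15; adjusted p = 0.599 with an estimated correlation). The mitotic kinase Plk1 went from 28.0 ± 1.3 to 5.77 ± 3.2 RPKM, Ccnb2 at log2 −2.19, the centromeric histone Cenpa at −2.15 and the thymidine kinase Tk1 at −2.07. The other large falls were Crabp1 (137 ± 37 to 21.4 ± 5.8 RPKM), the collagen chains Col6a3 (48.6 ± 1.6 to 8.38 ± 2.4) and Col6a1 (204 ± 29 to 41.7 ± 11), Rpl19 (1181 ± 86 to 231 ± 86), cyclin D1 (Ccnd1, 88.9 ± 12 to 16.5 ± 3.2), the imprinted RNA H19 (324 ± 25 to 63.3 ± 8.1), Mcpt8, Lrrc15 and Il1rl1. Akr1c14 (0.555 ± 0.16 to 21.2 ± 4.0 RPKM), the hypertrophic cartilage collagen Col10a1 (8.88 ± 0.047 to 129 ± 7.5), Arg1 (1.66 ± 0.23 to 21.6 ± 5.1), the collagenase Mmp13 (log2 2.78) and the imprinted gene Mest (log2 2.76) were among the large rises. In siGcn5 replicates 1 and 2 without dox Rpl19 was at 170 and 292 RPKM and Isg15 at 149 and 74.8, and with dox Rpl19 was at 367 and 664 and Isg15 at 73.3 and 21. In the same replicates Kat2a was at 1.33 and 1.97 RPKM without dox and at 6.27 and 9.11 with dox. Whether this difference bears on the calls that rested on replicate 1 was not tested.

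Interferon genes rose in 23 of 29 cases with siGcn5 without dox (25 adjusted over the list alone; median 1.46, adjusted p = 0.00078; adjusted p = 0.905 with an estimated correlation), with a median of 0.90 without siGcn5 replicate 1 (adjusted p = 0.0146). Oas1a was at log2 2.65, Oasl2 at 2.49, tetherin (Bst2) at 1.97 and Xaf1 at 1.90. Of 25 p53 and arrest genes 19 rose (median 0.60, adjusted p = 0.00078; adjusted p = 0.599 with an estimated correlation). Cdkn1c was at log2 1.73, Trp53inp1 at 1.44 and the cell cycle inhibitor p21 (Cdkn1a) from 181 ± 7.6 to 428 ± 50 RPKM. Mesenchymal genes fell in 19 of 34 and rose in 2 (median −0.31, adjusted p = 2.3e-05; adjusted p = 0.697 with an estimated correlation). S100a4 was at log2 −1.68 and Thy1 at −1.52. Among 58 splicing regulators 26 fell, 9 rose and 23 did not pass the test (median −0.15, adjusted p = 0.00078; adjusted p = 0.599 with an estimated correlation). Hnrnpa1 was at log2 −0.86, Hnrnpd at −0.83 and Rbm38 at 1.20. Of 30 nucleotide and one-carbon genes 11 fell and 5 rose (median −0.13, adjusted p = 0.0302; adjusted p = 0.905 with an estimated correlation). Psat1 was at log2 −1.14. Without genes that hold an siRNA heptamer the calls of splicing regulators and nucleotide genes both ended (adjusted p = 0.132 for each), and that of nucleotide genes also ended without siControl replicate 1 (0.0695). The medians of these 2 lists were −0.30 and −0.27 with median-ratio scaling, and −0.045 and −0.040 without heptamer genes. That of nucleotide genes was −0.075 without siControl replicate 1. The core spliceosome (19 up, 9 down or 8 adjusted over the list alone, median 0.09, adjusted p = 0.893) and ribosome biogenesis (9 up or 7 adjusted over the list alone, 4 down, median 0.09, adjusted p = 0.928) had medians that turned negative under median-ratio and quantile scaling, and their tests pointed down. Ribosomal protein genes fell in 11 of 53 and rose in 4 (3 adjusted over the list alone), with a median of −0.04 that turned positive under quantile normalization (adjusted p = 0.0570). With the replicate block this list passed as lower. The list passed as lower with median-ratio scaling (median −0.19, 0.0073), a mean RPKM of at least 5 (0.0311), array weights (0.0497) and voom (0.0463), and without heptamer genes (0.0244), siControl replicate 1 (0.0123), siGcn5 replicate 2 (0.0228) or either siGcn5 library with dox (0.0462 for each). Besides Rpl19, Rpl3 (log2 −1.33) and Rpl5 (log2 −1.15) fell. Epithelial genes rose in 11 of 20 and fell in 1 (median 0.32, adjusted p = 0.0655). That list passed as higher with median-ratio scaling (0.0073), quantile normalization (0.0284), a mean RPKM of at least 5 (0.0130), no filter (0.0207), a pseudocount of 0.1 (0.0257) and voom (0.0463), and without heptamer genes (0.0401), siControl replicate 1 (0.0491) or siGcn5 replicate 2 (0.0289). Krt18 was at log2 2.28 and Krt8 at 1.71. Of the falling genes named here, Col6a3, Il1rl1, Lrrc15, Ccnd1, Ccnb2, Hnrnpa1 and Hnrnpd hold an siGcn5 heptamer in the 3′ UTR, as do the rising Col10a1, Arg1, Mmp13, Trp53inp1 and Xaf1. Across all genes with a 3′ UTR, 40.1% hold one. Among called genes with a 3′ UTR, 49.6% of those that fell hold one, against 36.0% of those that rose. For changes of at least 2-fold the shares were 50.7% and 31.7%. The heptamers were chosen on values of these libraries, which favours such a gap. In all, 7554 of 13175 genes were called, 4864 up and 2690 down. The median of all genes rose by 0.11 log2, and 64.4% of calls were rises, against 49.5% with median-ratio scaling and 54.0% with quantile normalization.

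The siGcn5 effect with dox asked which parts of the induced response needed Gcn5. Proliferation genes fell in 34 of 35 cases (median −1.44, adjusted p = 8.5e-13; adjusted p = 0.613 with an estimated correlation). Plk1 went from 55.8 ± 3.1 to 15.7 ± 7.6 RPKM, Cenpa at log2 −1.83, Tk1 at −1.79, Bub1b at −1.78 and Mcm5 at −1.76. Splicing genes were lower too. Among 58 splicing regulators 39 fell, 5 rose and 14 did not pass the test (median −0.43, adjusted p = 2.5e-08; adjusted p = 0.148 with an estimated correlation). Hnrnpd was at log2 −1.01 (SE 0.17, adjusted p = 0.00070), Hnrnpa3 at −0.97 (SE 0.10, adjusted p = 4.8e-05) and the muscleblind protein Mbnl2 at 0.97. Of 56 core spliceosome genes 37 fell (38 adjusted over the list alone) and 2 rose (median −0.37, adjusted p = 4.7e-08; adjusted p = 0.613 with an estimated correlation). Lsm2 was at log2 −1.06, Lsm5 at −1.02 and Snrpa1 at −0.85. The large rises included Col10a1 (2.93 ± 0.14 to 78.7 ± 11 RPKM), Isg15 (2.64 ± 0.67 to 47.2 ± 37), the interleukin 1 receptor antagonist Il1rn (2.00 ± 0.32 to 26.2 ± 4.8), C1qtnf3 (log2 2.97), Lgals3bp (log2 2.97), Arg1 (log2 2.82) and Msx2 (log2 2.81). H19 fell most after Kat2a (92.0 ± 0.63 to 19.3 ± 0.13 RPKM). Spc24 was at log2 −1.82 and Uhrf1, which binds hemimethylated DNA, at −1.80.

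Interferon genes rose in 24 of 29 cases with siGcn5 and dox (25 adjusted over the list alone; median 1.67, adjusted p = 3.2e-06; adjusted p = 0.613 with an estimated correlation, and a median of 2.89 with voom). Usp18 was at log2 3.24, Oas1a at 2.48 and Irf7 at 2.39. Ribosome biogenesis genes fell in 25 of 43 (29 adjusted over the list alone; median −0.39, adjusted p = 3.7e-06; adjusted p = 0.613 with an estimated correlation). Pno1 was at log2 −0.98 and Lyar at −0.93. Ribosomal protein genes fell in 27 of 53 (23 adjusted over the list alone; median −0.25, adjusted p = 1.5e-06; adjusted p = 0.613 with an estimated correlation, and a median of −0.17 without siGcn5 replicate 1). Rpl19 went from 1550 ± 5.3 to 515 ± 210 RPKM and Rpl3 was at log2 −1.10. Quantile normalization ended the call of this list (median −0.059, adjusted p = 0.234). Of 30 nucleotide and one-carbon genes 23 fell and 1 rose (median −0.52, adjusted p = 3.0e-06; adjusted p = 0.613 with an estimated correlation). Prps2 was at log2 −1.03. Of 25 p53 and arrest genes 14 rose (15 adjusted over the list alone) and 2 fell (median 0.33, adjusted p = 0.0081; adjusted p = 0.613 with an estimated correlation). Cdkn1c was at log2 1.90 and Cdkn2b at 1.53. Mesenchymal genes rose in 19 of 34 and fell in 5 (median 0.29, adjusted p = 0.0085; adjusted p = 0.613 with an estimated correlation). Postn was at log2 2.04, fibronectin (Fn1) at 1.65, Col5a2 at 1.57 and Pdgfrb at 1.52. Of 15 inflammatory genes 10 rose and 2 fell (median 0.95, adjusted p = 0.0441; adjusted p = 0.613 with an estimated correlation). The chemokines Ccl20 and Ccl2 were at log2 1.81 and 1.64. Without genes that hold an siRNA heptamer the calls of mesenchymal (adjusted p = 0.236) and p53 genes (0.0546) ended, although both medians stayed within 1.5 times of those reported. The inflammatory call ended without siControl replicate 2 (0.0822) or siGcn5 replicate 1 (0.0679). Epithelial genes went both ways, 6 up and 6 down of 20 (median 0.00, adjusted p = 0.944). The ER stress genes Ddit3 (16.1 ± 0.29 to 64.5 ± 14 RPKM) and Ppp1r15a (log2 1.52) rose, in a list that did not pass (10 up, 4 down of 19, adjusted p = 0.214). Of the falling genes named here, Hnrnpd, Hnrnpa3, Lsm2, Snrpa1 and Prps2 hold an siGcn5 heptamer, as do the rising Col10a1, Arg1, Fn1, Postn, Col5a2, Pdgfrb, Ccl20 and Irf7. Across all genes with a 3′ UTR, 40.1% hold one. Among called genes with a 3′ UTR, 44.1% of those that fell hold one, against 36.9% of those that rose. For changes of at least 2-fold the shares were 37.0% and 33.8%. In all, 7412 of 13175 genes were called, 4136 up and 3276 down.

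The interactions asked whether an siRNA effect differed between the dox states. With siMyc, 7129 genes were called, 3267 with a more positive effect with dox and 3862 with a more negative effect. Notum (0.178 ± 0.048 RPKM in siMyc without dox and 24.3 ± 1.8 with dox, against 0.286 and 0.776 in siControl; log2 difference 3.96, SE 0.14, adjusted p = 4.6e-07), Ccdc114 (3.37), Cdsn (3.34), the osteocalcin gene Bglap2 (3.26) and the tetraspanin Cd82 (3.17) had the most positive differences among the genes chosen, and Ccnb1ip1 (−3.43), Anxa10 (−2.74), Car12 (−2.73) and Gldc (−2.59) the most negative. The effect was more negative with dox in all 43 ribosome biogenesis genes (median difference −1.18, adjusted p = 4.2e-14; adjusted p = 0.455 with an estimated correlation), in 54 of 56 core spliceosome genes (median −0.78, adjusted p = 4.2e-14; adjusted p = 0.455 with an estimated correlation) and in 35 of 58 splicing regulators, with 2 more positive (3 adjusted over the list alone; median −0.54, adjusted p = 2.2e-05; adjusted p = 0.455 with an estimated correlation). It was more positive in 26 of 34 mesenchymal genes and more negative in 1 (median 0.96, adjusted p = 2.6e-08; adjusted p = 0.455 with an estimated correlation).

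With siGcn5, 3409 genes were called for the interaction, 1500 more positive and 1909 more negative with dox. Rises made up 44.0% of these calls, and 57.0% with median-ratio scaling. Spp1 (2.25), Col6a1 (2.10) and Postn (2.05) had positive differences, and Mest (−3.25, with 63.2 ± 1.7 RPKM in siGcn5 without dox and 34.3 ± 7.4 with dox, against 8.49 and 48.0 in siControl), Akr1c18 (−2.23), Krt8 (−2.04) and Klk14 (−1.98) negative ones. The effect was more positive with dox in 25 of 34 mesenchymal genes (28 adjusted over the list alone; median 1.03, adjusted p = 1.4e-16; adjusted p = 0.543 with an estimated correlation) and more negative in 28 of 56 core spliceosome genes (36 adjusted over the list alone; median −0.38, adjusted p = 5.2e-09; adjusted p = 0.543 with an estimated correlation) and in 17 of 43 ribosome biogenesis genes (22 adjusted over the list alone; median −0.47, adjusted p = 3.0e-06; adjusted p = 0.543 with an estimated correlation). For splicing regulators it was more negative in 9 of 58 and more positive in 1 (6 and 1 adjusted over the list alone; median −0.21, adjusted p = 0.0070; adjusted p = 0.543 with an estimated correlation), a call that ended under quantile normalization (0.100) and without genes that hold an siRNA heptamer (0.0797). The count of genes was 1677 and 1917 without siControl replicates 2 and 1 without dox, 1734 without siGcn5 replicate 1 without dox, 1769 without siControl replicate 2 with dox, and 2232 without siGcn5 replicate 1 with dox.

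The size of the dox response was compared over genes chosen in the arm left out of each comparison. Over 7693 genes called for dox in siGcn5, the rising minus falling score went up with dox by 1.61 log2 in siControl, from −0.576 ± 0.025 to 1.04 ± 0.067 (SD, n = 2), and by 0.79 in siMyc, from −0.815 ± 0.0091 to −0.0206 ± 0.087. The siMyc response was 49.2% of that in siControl, a difference of −0.82 (fry, adjusted p = 0.00053 over the 2 comparisons, from limma). Of these genes, 4324 (56.2%) responded less in siMyc or the opposite way and 728 (9.46%) responded more in the same direction, by the interaction test. Over 5899 genes called for dox in siMyc, the score rose by 1.41 in siControl and by 0.94 in siGcn5, from −0.782 ± 0.043 to 0.155 ± 0.12, which is 66.6% and a difference of −0.47 (fry, adjusted p = 0.00053 from limma). This difference was −0.29 under quantile normalization and −0.97 over genes chosen with a 2-fold minimum. Here 1622 genes (27.5%) responded less in siGcn5 or the opposite way and 364 (6.17%) more in the same direction.

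**Figure D3:**
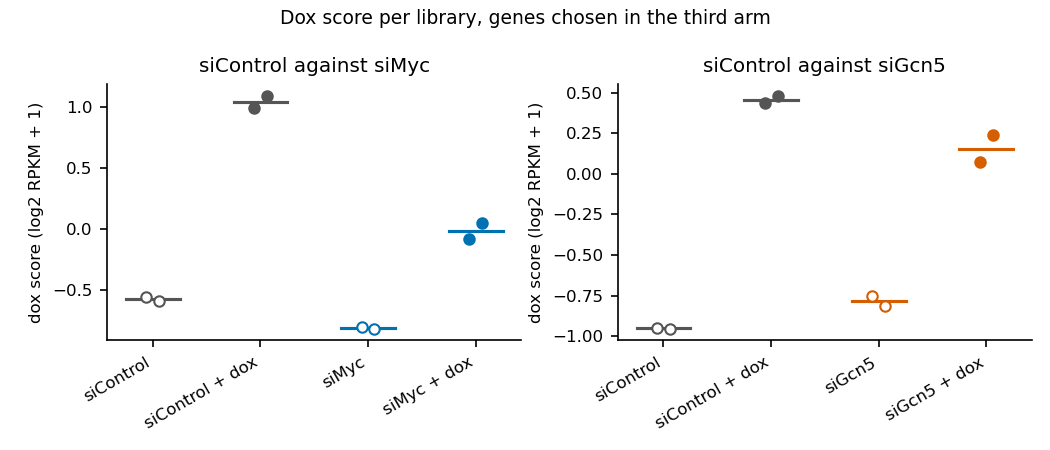
Dox score per library (mean log2(RPKM + 1) of the rising genes minus that of the falling genes, genes chosen in the arm not shown), for siControl and siMyc in the first panel and siControl and siGcn5 in the second, with points for libraries and lines for group means. With dox the siControl libraries average 1.04 and the siMyc libraries −0.0206 in the first panel, and siControl 0.457 and siGcn5 0.155 in the second.

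With dox, siMyc and siGcn5 were also compared with each other. Ribosome genes were lower in siMyc. Ribosome biogenesis genes were lower in 42 of 43 cases (median −1.47, adjusted p = 5.9e-13; adjusted p = 0.399 with an estimated correlation). Rrp9 was at log2 −2.11 and Polr1a at −1.87, and ribosomal protein genes in 49 of 53 (50 adjusted over the list alone), with 1 higher (median −0.80, adjusted p = 6.5e-10; adjusted p = 0.432 with an estimated correlation, and a median of −0.42 under quantile normalization). Bglap2 (527 ± 21 RPKM in siMyc and 23.8 ± 3.5 in siGcn5), Cdsn (74.1 ± 4.1 and 2.98 ± 0.28), Bglap (163 ± 2.9 and 8.61 ± 1.2), Nkain4 (log2 3.96), Notum (log2 3.88) and Fgf3 (log2 3.73) were higher in siMyc. Col10a1 (2.53 ± 0.19 and 78.7 ± 11 RPKM), Car12 (log2 −3.37), Ogn (log2 −3.30), Il1rn (log2 −3.20), Ptn (log2 −2.71) and Fabp7 (log2 −2.52) were lower. Klf4 was higher in siMyc (log2 0.94, adjusted p = 0.00031), Pou5f1 lower (log2 −0.60, adjusted p = 0.0094, a call that ended without siMyc replicate 1, at 0.0845, or siGcn5 replicate 2, at 0.0828), and Sox2 did not pass the test (log2 −0.14, near 0 at 0.00 with median-ratio scaling, adjusted p = 0.594). Without siGcn5 replicate 1 the Sox2 difference passed (log2 −0.57, adjusted p = 0.0085).

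Core spliceosome genes were lower in siMyc in 52 of 56 cases (median −0.65, adjusted p = 1.0e-09; adjusted p = 0.399 with an estimated correlation). Snrnp40 was at log2 −1.90 and Snrpg at −1.37. Of 58 splicing regulators 32 were lower and 5 higher (median −0.28, adjusted p = 0.0181; adjusted p = 0.399 with an estimated correlation). Prmt5 was at log2 −1.74 (SE 0.11), Rbm38 at −1.16, Hnrnpa1 at −0.91 and Celf2 at 0.97. Of 30 nucleotide and one-carbon genes 26 were lower and 1 higher (median −0.93, adjusted p = 9.1e-06; adjusted p = 0.432 with an estimated correlation). Shmt1 was at log2 −2.28 and Cad at −2.08. Of 25 p53 and arrest genes 18 were lower and 1 higher (median −0.78, adjusted p = 0.00095; adjusted p = 0.399 with an estimated correlation). Trp53inp1 was at log2 −2.18 and the p53 ligase Mdm2 at −1.57. Cholesterol synthesis genes were higher in 13 of 22 and lower in 2 (median 0.59, adjusted p = 0.0035; adjusted p = 0.558 with an estimated correlation). Tm7sf2 was at log2 2.12. Mesenchymal genes were higher in 17 of 34 and lower in 8 (9 adjusted over the list alone; median 0.24, adjusted p = 0.0073; adjusted p = 0.501 with an estimated correlation). Their median was 0.38 without siGcn5 replicate 1, 0.10 without siGcn5 replicate 2, 0.38 and 0.40 with median-ratio and quantile scaling, and 0.58 without heptamer genes. Dcn was at log2 2.21 and Sparc at 1.81. Of 20 glycolysis genes 11 were lower and 1 higher (median −0.41, adjusted p = 0.0342; adjusted p = 0.399 with an estimated correlation). Ldha was at log2 −1.17. The calls of splicing regulators and glycolysis ended with median-ratio scaling (medians −0.13 and −0.26, adjusted p = 0.0735 and 0.0732). They also ended without siGcn5 replicate 2 and without genes that hold an siRNA heptamer (0.110 and 0.346). That of glycolysis ended under quantile normalization (0.0937) and with a mean RPKM of at least 5 (0.189) as well. The glycolysis median was −0.153 with that minimum and −0.148 without heptamer genes. Proliferation genes were lower in 5 of 35 (3 adjusted over the list alone; median −0.07, positive under median-ratio and quantile scaling, adjusted p = 0.934), and without siGcn5 replicate 1 the list passed (median −0.47, adjusted p = 0.0440). Interferon genes were lower in 6 of 29 and higher in 2 (median −0.51, adjusted p = 0.411), and without siGcn5 replicate 2 that list passed too (median −1.06, adjusted p = 0.0031). In all, 8687 genes were called, 3599 higher and 5088 lower in siMyc. Of the genes named as lower in siMyc, Car12, Ogn, Polr1a and Trp53inp1 hold heptamers of both siRNAs, and of those named as higher, Klf4, Celf2, Dcn and Sparc hold an siGcn5 heptamer. The share higher was 41.4%, and 53.6% with median-ratio scaling.

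The siMyc and siGcn5 effects were set side by side to ask how far they covered the same genes. With dox, 2647 genes rose in both against 1561 for independent lists, 2316 fell in both against 1217, and 924 went opposite ways against 2773. The covariance of log2 changes across 13175 genes was 0.245, against 0.00735 in simulations of unchanged groups with the same controls (highest 0.00785), a difference of 0.238, and the correlation was 0.542 against 0.499. Without dox, 826 genes rose in both against 622, 402 fell in both against 288, and 655 went opposite ways against 866, with a covariance of 0.0428, a difference of 0.0355 from the simulated mean, and a correlation of 0.249 against 0.499 in the simulations, whose highest was 0.521. The simulated values leave out real effects and the independent lists leave out the shared controls, genes are not independent replicates, and 2 control libraries cannot be split, so part of the excess may come from the shared controls. Without dox, the genes that rose and fell in both numbered 272 and 150 without siControl replicate 1, 361 and 160 without siControl replicate 2, 281 and 139 without siMyc replicate 1, and 1346 and 650 with array weights.

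**Figure D4:**
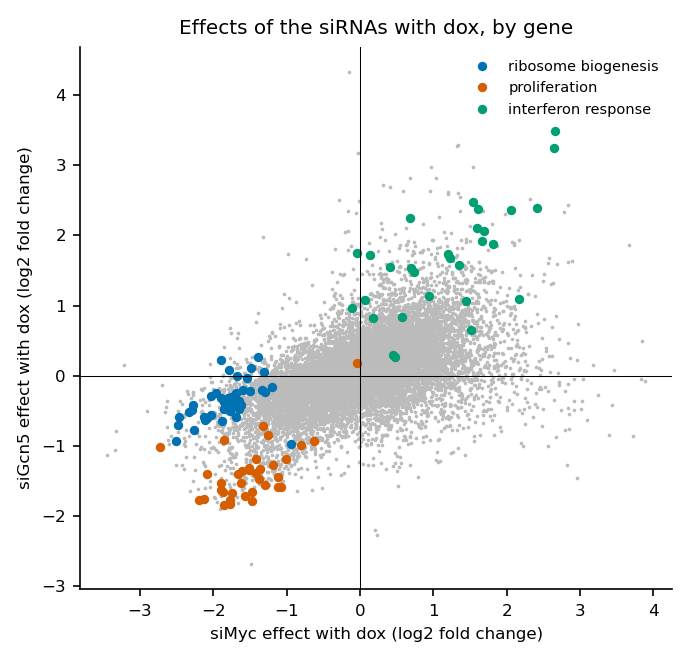
Log2 change of each of 13175 genes with siGcn5 against its log2 change with siMyc, both with dox and against the same siControl libraries, with all genes in grey and the ribosome biogenesis, proliferation and interferon lists in colour. Ribosome biogenesis genes have a median of −1.77 with siMyc and −0.39 with siGcn5, proliferation genes −1.51 and −1.44, and interferon genes 1.22 and 1.67.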

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

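Most results in this part are those where an siRNA effect differed between the dox states by the interaction test. The genes that fell at least 2-fold in both dox states and the higher interferon genes with siGcn5 were not chosen by that test. Chosen only after the results were seen were the tests of large falls against sets matched on 3′ UTR length, of larger dox responses with siMyc, of blood markers and of a response to the duplex, the interval set beside the shared runs, and the fit without genes that hold an siRNA heptamer. The heptamer values given here come from the covariates and the two-sided threshold as first written, while the heptamer sets come from the fit run first, whose one-sided threshold and added covariates were settled after its t values were seen.

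With siMyc, 7129 genes had an effect that differed between the dox states. The log2 difference was −1.05 for Myc, −1.15 for Kat2a and −1.29 for Pou5f1. That of Sox2 was −0.84 (adjusted p = 0.0439, and 0.00269 to 0.448 over the alternatives), a call that ended without any siControl library (0.0545 to 0.129), either siMyc library without dox (0.0908 and 0.0889), siMyc replicate 1 with dox (0.133) or either siGcn5 library without dox (0.0507 for each), and under both other scalings (0.0686 and 0.0708). Among the genes the naming rule takes, the most positive differences were those of Notum (3.96), Ccdc114 (3.37), Cdsn (3.34), Bglap2 (3.26) and Cd82 (3.17), and the most negative those of Ccnb1ip1 (−3.43), Anxa10 (−2.74), Car12 (−2.73), Gldc (−2.59) and Smpdl3b (−2.58). List medians were −1.18 for ribosome biogenesis, −0.78 for the core spliceosome, −0.54 for splicing regulators and 0.96 for mesenchymal genes. Ribosomal protein genes had a more negative effect with dox in 21 of 53 cases (18 adjusted over the list alone; median −0.36, adjusted p = 7.3e-05; adjusted p = 0.656 with an estimated correlation, and a median of −0.20 under quantile normalization). Nucleotide and one-carbon genes did in 26 of 30 (median −0.98, adjusted p = 1.7e-07; adjusted p = 0.455 with an estimated correlation) and proliferation genes in 31 of 35 (32 adjusted over the list alone; median −1.28, adjusted p = 8.9e-07; adjusted p = 0.561 with an estimated correlation). ER stress genes had a more positive effect in 9 of 19 and a more negative one in 1 (median 0.32, adjusted p = 0.0090; adjusted p = 0.561 with an estimated correlation), and this call ended without genes that hold an siRNA heptamer (0.0534; 0.00324 to 0.0534 over the alternatives other than the estimated correlation).

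With siGcn5, 3409 genes had an effect that differed between the dox states. Pou5f1 was at −1.44, with a log2 change of 0.75 (adjusted p = 0.0034) without dox and −0.69 (adjusted p = 0.0059) with dox. By the same rule the most positive differences were those of Prl2c4 (3.22), Prl2c3 (3.21), Spp1 (2.25), Col6a1 (2.10) and Postn (2.05). The most negative were those of Mest (−3.25), Akr1c18 (−2.23), Krt8 (−2.04), the melanocyte gene Mlana (−2.002, at 6.87 ± 3.7 RPKM in siGcn5 without dox and 1.19 ± 0.52 with dox) and Klk14 (−1.98). List medians were −0.21 for splicing regulators, −0.38 for the core spliceosome, −0.47 for ribosome biogenesis and 1.03 for mesenchymal genes. Epithelial genes had a more negative effect with dox in 7 of 20 cases (8 adjusted over the list alone) and a more positive one in 1 (median −0.37, adjusted p = 0.0102; adjusted p = 0.543 with an estimated correlation, and a median of −0.77 with a pseudocount of 0.1 and −0.99 with voom). Inflammatory genes had a more positive effect in 6 of 15 (8 adjusted over the list alone; median 0.70, adjusted p = 0.00047; adjusted p = 0.543 with an estimated correlation, and a median of 0.45 without siGcn5 replicate 1 with dox) and ER stress genes in 5 of 19 (median 0.30, adjusted p = 0.0063; adjusted p = 0.543 with an estimated correlation, and a median of 0.19 without siControl replicate 1 without dox). Without genes that hold an siRNA heptamer both calls ended, at 0.0582 (1.3e-05 to 0.0582 over the alternatives other than the estimated correlation) and 0.0797 (0.000701 to 0.0797). The ER stress median was then 0.0985, while the inflammatory median stayed within 1.5 times of that reported.

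The siGcn5 medians of ribosomal protein genes (−0.22, 0 of 53 called, adjusted p = 0.0155; adjusted p = 0.757 with an estimated correlation) and of nucleotide genes (−0.31, 4 of 30 more negative or 3 adjusted over the list alone, adjusted p = 0.0140; adjusted p = 0.621 with an estimated correlation) rested on some libraries. The first call ended without siControl replicate 1 without dox (0.115), siControl replicate 2 with dox (0.0510), siGcn5 replicate 2 without dox (0.149) or siGcn5 replicate 1 with dox (0.416), under both other scalings (0.0755 and 0.153) and without heptamer genes (0.0582), with 0.000191 to 0.416 over the alternatives other than the estimated correlation. The second ended without siControl replicate 2 with dox (0.0560), siGcn5 replicate 1 with dox (0.230) and under quantile normalization (0.0886), with 0.000536 to 0.230 over the same alternatives.

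Among the 11159 tested genes with a transcript sequence in the annotation, which leaves out the targeted gene and others such as H19, 193 fell at least 2-fold in both dox states with siGcn5 and 23 with siMyc. Near-complete pairing of an siGcn5 duplex with at least 10% of the 193 transcripts, as predicted, was argued against. Of the 193, 6 (3.11%, exact 95% interval 1.15 to 6.64%, which covers counting error only), Rpl19 and Bub1 among them, shared a run of 15 or more bases with Kat2a, against 3.00% of the 11159 genes. The outcome predicted without such pairing, a share at or below that of all genes, was not met either. Pairing with single transcripts stays open, and Rpl19 shared a run of 16 bases, with a run as long in 102 of the 11159 genes. Across all genes with a 3′ UTR, seed pairing was consistent with the heptamers that passed a t of 4.67 in both dox states and lay in the target's transcript, GTCAATG for siGcn5 (t −11.0 without dox and −6.13 with dox) and ACAACTA for siMyc (−4.94 and −5.36), although under the first fit's covariates ACAACTA missed that threshold without dox (−4.63) and CACAACT passed in both (−7.17 and −4.73). Of the 193 genes, 74 (38.3%, against 40.1% of all genes) held an siGcn5 heptamer, narrowly above the 25.9 to 37.3% of 10000 length-matched sets (median 31.6%), so seeds may add to some of these falls, while 119 genes held none and the loss of Gcn5 stays open for all. Of the 23 siMyc genes, 5 (21.7%) held an siMyc heptamer, equal to the upper bound of the matched sets with the first heptamers (21.7%) and above it with those chosen without the 23 genes (17.4%), so for these genes seed pairing and the loss of Myc cannot be told apart.

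Interferon genes were higher with siGcn5, at a median of 1.46 without dox and 1.67 with dox, and without siGcn5 replicate 1 of each state at 0.90 and 1.17. With dox, blood cells among the fibroblasts were argued against, because the tested blood markers Cd68, Lyz2 and Cd14 had a median of −0.36 and none rose. Cd14 fell (log2 −0.39) and Cd68 was at −0.36, a call that ended without siControl replicate 1 or siGcn5 replicate 1. The 9 untested markers reached at most 0.777 RPKM in the siGcn5 libraries. The tested markers were low as well, with Cd14 at most at 2.25 and Cd68 at most at 7.10 RPKM in any library, so this evidence is weak. For the state without dox the explanation stays open. Without dox Lyz2 was at log2 0.48 (adjusted p = 0.0248), a call that ended without siControl replicate 1 (0.227), siGcn5 replicate 1 (0.0657) or siGcn5 replicate 2 (0.0968). With dox, 18 of 29 interferon genes also rose with siMyc (median 1.22), so the rise was not seen with siGcn5 alone. Without dox the siMyc median was 0.72, with 1 of 29 called. In siControl the list fell with dox (median −0.92). The list test of siMyc against siGcn5 with dox did not pass (median −0.51, adjusted p = 0.411). Its median was −1.06 without siGcn5 replicate 2. A common cause of the rise with both siRNAs was not tested. A response to the transfected duplex itself and one to the loss of Gcn5 both allow the siGcn5 median of 1.67. They cannot be told apart, since each siRNA arm has 1 label. The list test with dox gave adjusted p-values of 1.2e-09 to 0.000169 over the alternatives and 0.613 with an estimated correlation.

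The dox response differed in size from that in siControl by −0.82 with siMyc and by −0.47 with siGcn5 (−0.29 under quantile normalization and −0.97 over genes chosen with a 2-fold minimum). For siMyc, a lower amount of the introduced factors that scales every response down alike was set against the share of larger responses. Of 7693 genes, 728 (9.46%, exact 95% interval 8.82 to 10.1%, which covers counting error only) had a larger response in the same direction, so these genes were not scaled down. The limit of under 5% for that explanation was chosen after the results were seen. Seed pairing or a shift of all RPKM values could also enlarge a response, so the share cannot decide it. With siMyc and dox Klf4 was at 144 RPKM against 105 in siControl and Pou5f1 at 110 against 268. A lower amount of some factors that acts unevenly on their targets, and a need for Myc itself, also stay open and were not tested.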

How the results depend on the processing

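Limma voom on recovered reads, thinned reads and the fit without heptamer genes were tests chosen only after the results were seen. No named gene that was called and no list that passed its test changed direction under any alternative run for it. Medians of some lists that did not pass changed sign under another scaling, and the share of rises among called genes crossed 50% under median-ratio scaling or quantile normalization in each comparison except siMyc without dox. Under array weights, voom, median-ratio scaling, quantile normalization, no filter, the stricter filter, no trend, a pseudocount of 0.1, thinned reads and only the groups compared, 8 of 8 counts of called genes stayed within 1.5 times of those reported (with voom 9860, 3523, 9778, 7765, 7353, 6912, 3396 and 8574 for dox in siControl, siMyc without and with dox, siGcn5 without and with dox, the siMyc and siGcn5 interactions, and siMyc against siGcn5). A minimum of 2-fold, which by its construction calls fewer genes, left 2602, 107, 2913, 971, 913, 1739, 401 and 1773 in the same order. Without the 4929 genes that hold an siRNA heptamer, the counts were 6071, 1810, 6200, 4548, 4486, 4487, 2055 and 5368 of 8246 genes, since fewer were tested. With array weights 1346 genes rose and 650 fell with both siRNAs without dox, and the cause was not tested. Leaving out each library in turn kept 88 of 96 counts within 1.5 times, although a group then has 1 library, which is assumed to vary like the others. The counts ran from 1072 (without siMyc replicate 1 without dox) to 3481 (without siGcn5 replicate 2 with dox) for siMyc without dox, and from 1677 (without siControl replicate 2 without dox) to 3960 (without siGcn5 replicate 2 with dox) for the siGcn5 interaction. Genes that rose with both siRNAs without dox ran from 272 (without siControl replicate 1 without dox) to 968 (without siGcn5 replicate 1 with dox), and those that fell with both from 139 (without siMyc replicate 1 without dox) to 517 (without siGcn5 replicate 1 with dox). The cause of these shifts was not tested. The difference in dox response size ran from −1.16 to −0.71 for siMyc and from −0.97 to −0.29 for siGcn5 over the alternatives. Of 176 list tests, the estimated correlation ended 75, heptamer genes left out 17, quantile normalization 9 and median-ratio scaling 4. Leaving out a library ended a list call in 17 of 2112 refits and added one in 26, and for named genes it ended a call in 250 of 7476 and added one in 11. Many of these refits left out a library outside the comparison tested, which leaves its log2 changes as they were. Many of the tests were also not called to begin with and could not lose a call. The shares of refits given here, that of the counts included, therefore overstate how stable the calls were. Depth limits low genes most, and thinning every library to 65.5 M reads changed none of the 8 counts by over 1.5 times.

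With the replicate block the counts were 10373, 4440, 10445, 8489, 8381, 8287, 5061 and 9490 in the same order, each within 1.5 times of that reported, and without dox 1394 genes rose and 653 fell with both siRNAs. Deviations of same-numbered libraries correlated at 0.0933 to 0.489 over 15 pairs of groups, 14 of them above 0.1, and the labels tie the numbers to nothing shared. All 15 were positive, so an effect shared by libraries of the same number is not excluded. The main fit was planned without the block and leaves such an effect out. The block ended no list call and added 4, SAGA genes with siMyc without dox (adjusted p = 0.0446), ribosomal protein genes with siGcn5 without dox (0.0286) and cholesterol synthesis with siGcn5 without and with dox (0.0411 and 0.0085), all as lower.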

Other observations

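The list tests in this part were planned, and the shares of ribosomal and small nucleolar RNA were chosen only after the data were seen and carry no tests. Some genes of other lineages moved with dox in siControl. Tubb3, a neuronal tubulin, went from 21.9 to 149 RPKM, Stmn2 rose by 2.08 log2, and Tek, an endothelial receptor, went from 0.0396 to 8.11 RPKM, while the muscle genes Acta1 (log2 −1.10) and Des (log2 −1.02) and the fatty acid binding protein gene Fabp4 (log2 −2.58) fell. The lists themselves did not pass: 3 of 6 neural markers rose and 3 fell (median 0.77, adjusted p = 0.853), 2 of 5 endothelial markers rose and 2 fell (median −0.37 and mean 0.39, adjusted p = 0.801), 2 of 3 blood markers rose and 1 fell (median 0.32, adjusted p = 0.801), 2 of 4 skeletal muscle markers rose and 2 fell (median −0.26, adjusted p = 0.801), and 2 of 4 adipocyte markers rose and 1 fell (median 0.87, adjusted p = 0.801). In the Myc network 7 of 10 genes rose and 3 fell (median 0.49, adjusted p = 0.572), with Max, the partner of Myc, at log2 1.06 and the antagonist Mxi1 at 1.68. Of 7 tested pluripotency genes 4 rose and 2 fell (median 0.67, adjusted p = 0.801), with L1td1 from 0.00679 to 9.91 RPKM and Klf2 at log2 −1.36. Others of that list, Nanog, Zfp42, Sall4 and Lin28a among them, were too low to be tested.

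With siMyc and dox, L1td1 (log2 −1.38), Trim28 (log2 −1.26), Mxi1 (log2 −1.43), Max (log2 −0.74), Lpl, which splits plasma triglyceride (log2 −1.55), and the adipocyte factor Cebpa (log2 −1.52) fell, and Acta1 (47.8 to 252 RPKM), Des (log2 1.14) and the endothelial genes Esam (log2 2.50) and Flt1 (log2 1.69) rose. All 4 tested skeletal muscle markers rose (median 0.89, adjusted p = 0.0430, and adjusted p = 0.376 with an estimated correlation). Others of that list, Myod1, Myog, Myf5 and Myf6 among them, were too low to be tested. The list call ended without siMyc replicate 2 with dox and without heptamer genes (0.0713). It also ended under both other scalings (0.0522 and 0.0688), with a pseudocount of 0.1 (0.0673), with a mean RPKM of at least 5 (0.106) and with voom (0.0545). With siGcn5, Fabp7, a glial fatty acid binding protein, rose without dox (log2 2.06) and with dox (log2 2.35), the intermediate filament gene Nes fell (log2 −1.68 and −0.92), Pparg rose without dox (log2 1.44), and with dox Fabp4 rose (log2 2.18) and Lpl fell (log2 −1.23). Fabp4, Lpl and Nes hold an siGcn5 heptamer, and Flt1 holds heptamers of both siRNAs. With siGcn5 and dox the marker lists did not pass, at adjusted p = 0.242 for neural (1 up, 4 down of 6), 0.284 for blood (0 up, 2 down of 3) and 0.922 for adipocyte markers (2 up, 2 down of 4). Cholesterol synthesis had 2 genes up and 7 down of 22 (median −0.33, adjusted p = 0.0778). That list passed as lower with the replicate block (0.0085) and with no filter (0.0394), and without siControl replicate 1 or siGcn5 replicate 2 with dox. Its adjusted p ran from 0.0085 to 0.250 over the alternatives other than the estimated correlation.

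Small nucleolar RNA genes made up 5.69 to 6.46% of summed RPKM in the 4 siMyc libraries and 8.14 to 10.2% in the other 8. RPKM divides by length, which raises the share of such short genes. Of gene reads they made up 0.25 to 0.30% in the siMyc libraries and 0.37 to 0.51% in the other 8. Rn45s, the ribosomal RNA precursor, was at 2420 RPKM in siMyc replicate 2 with dox (1.41% of its gene reads) and at 93.7 to 590 RPKM in the other libraries.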
